A study of Homo sapiens with 5 samples.

How the data were processed

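Binding of NR2C2 was measured by ChIP-seq in MCF-7 cells, an established estrogen receptor positive breast adenocarcinoma line. Per the labels, 2 control samples were untreated, 2 samples were exposed for 48 hours to 40 nM of a FOXA1 siRNA, and 1 input sample served as background. The labels name no cells treated with a non-targeting siRNA, so any effect of transfection itself is part of the difference between the groups. Reads were aligned with BWA 0.7.12 to hg38 and peaks were called with MACS2 2.2.6, per the submitters' processing notes, which give tools and build without their settings. The deposited files are 1 peak list for the control samples against the input and 1 list for the siFOXA1 samples against the same input, and their names state that blacklisted regions were left out. How the replicates were pooled is not given in the sources used here. Each list holds 1 set of values per condition, so no value carries a replicate error and the spread between the replicates of a group could not be measured.

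Each line of the deposited lists gives a peak's start, end and summit, a score, a fold enrichment, and the −log10 of a p-value and of a q-value at the summit. The fold enrichment in the deposited lists is the authors' ratio of the ChIP pileup to the local input background at the summit. The −log10 p and −log10 q values are those of the authors' peak caller. The deposited score was checked against the −log10 q values and equals 10 times their value, to within 1 unit. The highest q-value listed was 0.0498 in the control list and 0.0482 in the siFOXA1 list. These values are the authors' own and were used to describe, rank or filter peaks within 1 list. Fold enrichments were not compared between the lists, and the closing section compares recovered pileups, which both lists scale to the same input. Peaks on chromosomes 1 to 22 and X were analysed.

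A control peak overlapped by at least 1 bp of a siFOXA1 peak was called shared, and any other control-only. A siFOXA1 peak without overlap was called siFOXA1-only. Overlaps were found with bedtools 2.31.1 and set beside 100 random placements of the siFOXA1 peaks within their chromosomes, and beside 100 placements that kept the distance of boundary peaks to a gene boundary. Shares have 95% Wilson intervals, which cover counting error over peaks or genes only. Medians were compared with a two-sided permutation test of 100000 resamples, and shares with Fisher's exact test (two-sided) and an odds ratio with its 95% interval. Mantel-Haenszel odds ratios were computed over deciles of fold enrichment. The intervals and p-values of these tests are across peaks within pooled lists, and peaks are not replicates. Scripts ran under Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.

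Genes were taken from an annotation of GRCh38.p14, the same assembly as hg38, which gives the first and last base of each gene without strand or exons. The planned promoter class was therefore replaced by a gene boundary, a summit within 1 kb of the first or last base of a protein-coding gene. One of these ends is the transcription start and the other the end of the gene, and which is which is not given. Other summits were called inside a gene or intergenic. The planned tests of forkhead and other DNA motifs and the random gene lists matched on GC content need a genome sequence, which was not used here. For 15 gene lists fixed before the data were examined, the share of members with a boundary peak was placed as a percentile among 10000 random lists of protein-coding genes of the same size. The share of members with a control boundary peak that also had a siFOXA1 boundary peak was placed among 10000 random lists matched on decile of control fold enrichment. A list above the 97.5th or below the 2.5th percentile is described as standing apart. No p-value was computed across genes. Genes that share a boundary were each counted.

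Distances of peaks to genes and gene boundaries are those of their summits. Named peaks were chosen by a rule fixed before the data were examined. They are the 8 strongest peaks of each class inside a gene or within 10 kb of a gene boundary, the nearest peaks of FOXA1 and NR2C2, up to 4 members of each gene list with the strongest control boundary peak, and the 8 luminal genes with the strongest control peak in the gene or within 10 kb of it. In each group the text prints a part of these. The strongest peaks of each class carry the symbol of the gene with the nearest boundary. Peaks of FOXA1, NR2C2 and members of gene lists carry the symbol of that gene. Its boundary need not be the nearest, and for PRPF40A, ORC4, STAT2 and NR1H2 that of a neighbouring gene was nearer. Genes named beyond this rule are said to be.

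The number of reads over each summit was recovered from the fold enrichment and the −log10 p of the deposited lists, since the peak caller's pileups are whole multiples of what 1 read is worth. All pileups entering the search came out whole to within 0.1 read. A unique read count was found for 99.9% of control and 99.7% of siFOXA1 peaks. The ChIP libraries held 1.44 times the reads of the input in control cells and 1.36 times in siFOXA1 cells, and in both lists the ChIP pileup had been scaled down to the depth of the input. The siFOXA1 depth was 0.941 times the control depth. Absolute library sizes are not known. On simulated data, the overlap step found 2000 of 2000 made overlaps among 4000 peaks, a Mantel-Haenszel odds ratio made as 2 came out as 2.08 over 40000 simulated peaks, and all 3889 unique read counts found among 3891 simulated peaks were right.

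Alternatives fixed before the data were examined changed the overlap that counts as shared, the peak threshold, the list length, the merging of nearby peaks, the sequences used, the boundary window, the gene types and the matching of random lists. Leaving out replicates was not possible with 1 list per condition. The comparison of siFOXA1-only with shared siFOXA1 peaks, and its alternatives, were added after the data had been seen.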

Results

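NR2C2, an orphan nuclear receptor also called TR4, was mapped by ChIP-seq in MCF-7 cells that were untreated (2 samples) or had been exposed for 48 hours to 40 nM of a FOXA1 siRNA (2 samples), with 1 input library for both groups. FOXA1 is a forkhead transcription factor that opens chromatin for the estrogen receptor in luminal breast cancer cells, and the comparison asks whether it acts as a pioneer factor for NR2C2. The files give 1 peak list per group, called against the input, and no values per replicate, so every comparison below is between 2 pooled lists. FOXA1 depletion itself was not measured in these lists. On chromosomes 1 to 22 and X the control list held 13365 peaks covering 6.23 Mb, and the siFOXA1 list held 8079 peaks covering 3.46 Mb. Among peaks with a recovered read count (13349 control and 8055 siFOXA1 peaks), the median was 50 reads over the summit in either list, with a range of 17 to 888 reads in the control list and 16 to 865 reads in the siFOXA1 list. Coordinates are in hg38.

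NR2C2 occupied its own gene and that of its closest relative in both groups. The peak at the NR2C2 gene lay on chromosome 3 from 14947094 to 14948589, with its summit 50 bp from a gene boundary and a fold enrichment of 60.6 in the control list. The siFOXA1 list held an overlapping peak. At NR2C1, which encodes the related receptor TR2, the control peak on chromosome 12 from 95072506 to 95073945 had a fold enrichment of 63.6 and was shared. The summit of the control peak nearest to FOXA1 lay 1050 bp outside the gene, and the peak ran on chromosome 14 from 37595407 to 37596506, with a fold enrichment of 3.80. The summit was 670 bp from a boundary of the neighbouring gene TTC6, and the siFOXA1 list held an overlapping peak.

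After FOXA1 siRNA the list of NR2C2 peaks was shorter by 39.6%. Of the 13365 control peaks, 6878 were shared (51.5%, 95% interval 50.6 to 52.3) and 6487 were control-only. Of the 8079 siFOXA1 peaks, 6986 overlapped a control peak and 1093 were siFOXA1-only (13.5%, 12.8 to 14.3). Randomly placed siFOXA1 peaks overlapped 0.312% of control peaks on average, and 3.22% when boundary peaks were placed at random gene boundaries. The shared percent rose to 78.8% when only control peaks with a −log10 q of at least 10 were asked for. A peak missing from a list had not passed the caller's threshold there, which does not show that NR2C2 was absent.

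The strongest NR2C2 sites were shared and the weaker ones largely were not. Among peaks inside a gene or within 10 kb of a gene boundary, the 8 strongest shared peaks had control fold enrichments from 106 to 128. They lay at PGAP3, which encodes an enzyme of GPI-anchor remodelling (chromosome 17, 39687616 to 39688485, fold 128), at NFXL1 (chromosome 4, 47914301 to 47915216, fold 117), at NDUFB7, a subunit of respiratory complex I (chromosome 19, 14571452 to 14572420, fold 115), and at LAS1L, CWC15, TMEM101, ZNF77 and INTS1. Of these 8 summits, those at PGAP3, NFXL1, NDUFB7, LAS1L, CWC15 and INTS1 were at gene boundaries, that at TMEM101 was inside a gene and that at ZNF77 was intergenic. The strongest control-only peak was inside a gene near the boundary of RAB4A, a small GTPase of endosomal recycling (chromosome 1, 229273658 to 229274180), with a fold enrichment of 17.3 and 99 reads. Within the same reach of genes, the next lay inside a gene nearest to ASCC1 with a fold of 12 and at a boundary of ZNF746 with 11.3. They were followed by peaks at a boundary of PCM1 with 11.1 and 2294 bp from PDLIM5 with 11.1. Peaks nearest to NEBL, SMS and TRAF3 completed the 8, with folds of 10.9, 10.8 and 10.7.

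The median control fold enrichment was 6.95 (interquartile range 4.90 to 11.9) for shared peaks and 4.01 (3.31 to 4.84) for control-only peaks. The difference of 2.94 gave a permutation p of 1e-05, the smallest that 100000 resamples can give, across peaks. The shared percent climbed from 17.3% in the weakest decile of control fold enrichment to 47.5% in decile 6, 96.4% in decile 9 and 99.9% in the strongest decile. Within the siFOXA1 list, shared peaks had a median fold enrichment of 5.64 and siFOXA1-only peaks 4.28, a difference of 1.36 with the same permutation p of 1e-05.

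**Figure D1:**
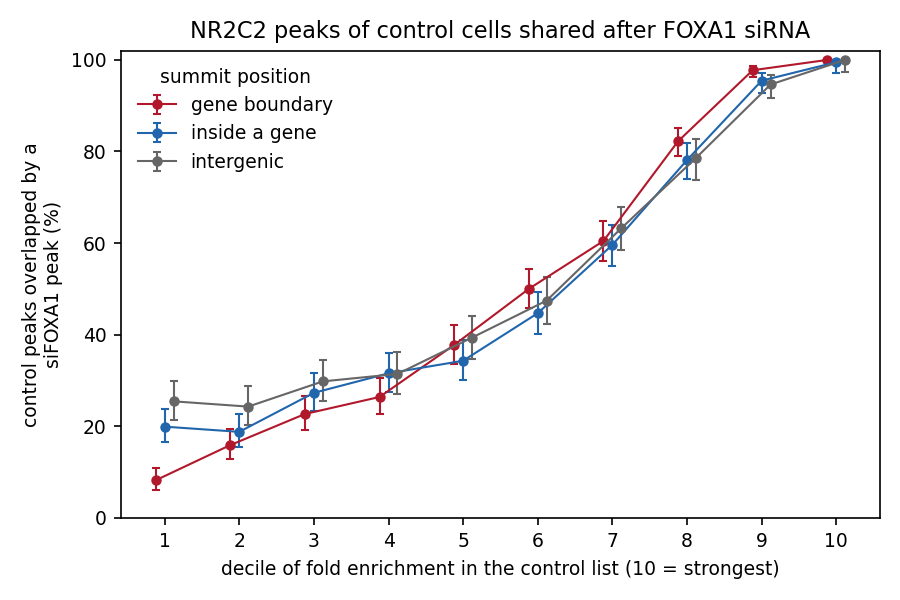
Percent of control peaks overlapped by a siFOXA1 peak (vertical axis) in each decile of control fold enrichment (horizontal axis, 10 the strongest), for summits at gene boundaries, inside genes and between genes, with bars for 95% Wilson intervals. In decile 1, 8.20% of boundary peaks and 25.4% of intergenic peaks were shared, and in decile 9, 97.7% and 94.6%.

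NR2C2 bound close to gene ends far more often than random placement would give. In the control list 42.3% of summits lay at a gene boundary, 31.1% inside a gene and 26.6% between genes, against 3.06% at a boundary for randomly placed peaks. In the strongest decile, 74.1% of summits were at a boundary. The whole siFOXA1 list had nearly the same boundary share, 41.7%. Among the 808 strongest peaks of each list, 81.9% (79.1 to 84.4) of control and 78.1% (75.1 to 80.8) of siFOXA1 summits were at a boundary, and among the 8079 strongest 46.1% (45.1 to 47.2) and 41.7% (40.6 to 42.8), lengths chosen after the data had been seen, and these differences were not tested. The boundary share was 46.5% (45.3 to 47.7) among shared peaks and 37.8% (36.6 to 39.0) among control-only peaks, an odds ratio of 1.43 (1.34 to 1.54, Fisher's exact p = 1.62e-24 across peaks). Within deciles of control fold enrichment the direction turned, with a Mantel-Haenszel odds ratio of 0.889 (0.814 to 0.971). With peaks within 500 bp merged it was 0.922 (0.842 to 1.01), an interval that reaches 1. The value of 0.889 joins an odds ratio of 0.634 (0.551 to 0.729) over the 4 weakest deciles and of 1.13 (1.01 to 1.27) over the other 6. That split was chosen after the deciles had been seen. With the list in 50 classes of strength, the odds ratio over the other 6 was 1.11 (0.99 to 1.25), an interval that reaches 1.

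Peaks found only after FOXA1 siRNA lay mostly away from gene ends. Of the 1093 siFOXA1-only peaks, 107 were at a gene boundary (9.79%, 8.17 to 11.7), 45.3% were inside genes and 44.9% between genes. Among the siFOXA1 peaks shared with control cells, 46.7% (45.5 to 47.9) were at a boundary. The odds ratio of shared against siFOXA1-only peaks was 8.08 (6.58 to 9.91, Fisher's exact p = 5.97e-137 across peaks), and 6.63 (5.38 to 8.18) within deciles of siFOXA1 fold enrichment. It fell to 2.09 when a shared peak had to overlap reciprocally by 50%, and to 2.71 when summits had to lie within 100 bp. Against control-only peaks, the odds ratio of a boundary among siFOXA1-only peaks was 0.179 (0.145 to 0.220, Fisher's exact p = 1.57e-86). The siFOXA1-only peaks named here were ranked only among those inside a gene or within 10 kb of a gene boundary. Intergenic peaks farther out were left out of the ranking. The strongest of those ranked were inside genes, far from the nearest boundary. The nearest boundary was that of LAMA4, a laminin chain of basement membranes, at a distance of 50847 bp for the first (chromosome 6, 112203935 to 112204323, fold enrichment 13.1, 56 reads). It was that of SLC24A2, at 309526 bp, for the second (chromosome 9, 19998170 to 19998554, fold 13.1, 56 reads) and that of ZNF609, at 107275 bp, for the third (chromosome 15, 64566648 to 64567011, fold 12.1). The others of the 8 were nearest to CYP11A1, the enzyme that starts steroid synthesis from cholesterol (fold 11.0), and to R3HCC1L, SPON1, TENM4 and DOCK9, with folds from 9.89 to 10.4. The summit near CYP11A1 was intergenic, 9420 bp from the gene boundary.

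**Figure D2:**
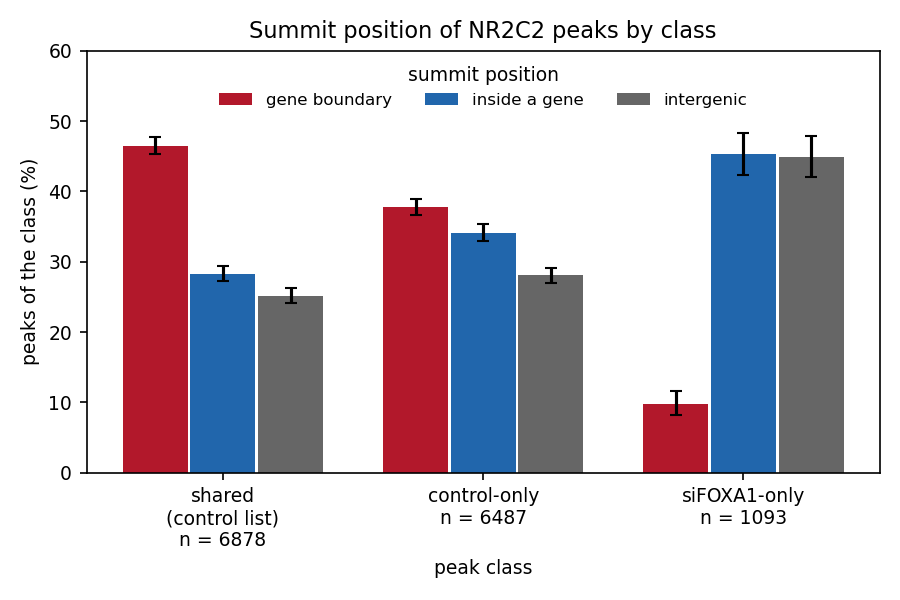
Percent of peaks (vertical axis) with the summit at a gene boundary, inside a gene or between genes, for shared, control-only and siFOXA1-only peaks, with bars for 95% Wilson intervals over peaks. The boundary share was 46.5% in shared, 37.8% in control-only and 9.79% in siFOXA1-only peaks.

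Genes of protein synthesis and mitochondrial respiration, among other lists, carried NR2C2 at their boundaries more often than protein-coding genes as a whole in both groups. Of 19974 protein-coding genes, 6302 (31.6%) had a boundary peak in the control list and 3934 (19.7%) in the siFOXA1 list. Among 77 mitochondrial ribosomal protein genes the shares were 80.5% and 61.0%, with control fold enrichments of 68.3 at MRPL53 and 64.4 at MRPS28. Among 88 oxidative phosphorylation genes they were 75% and 50%, led by NDUFB7 and by NDUFS1, another complex I subunit, whose peak with a fold of 70.3 it shares with the neighbouring gene EEF1B2. Among 83 cytosolic ribosomal protein genes they were 72.3% and 44.6%, with folds of 105 at RPS5 (chromosome 19, 58386598 to 58387762) and 78.4 at RPL32. Translation factors (62 genes) had 69.4% and 40.3%, including EIF3M with a fold of 70.1. Spliceosome genes (86) had 66.3% and 37.2%, proteasome subunits (40) 65% and 52.5%, and DNA replication and cell cycle genes (39) 64.1% and 41.0%, with folds of 56.4 at PRPF40A, 59.2 at PSMD14 and 54.1 at ORC4. The 517 ZNF genes had 46.6% and 32.5%, with a fold of 80.1 at ZNF3. Each of these 8 lists was at the 100th percentile of random lists in the control list and at the 99.9th or higher, after rounding, in the siFOXA1 list. The random lists were drawn from all protein-coding genes and were not matched on expression, open chromatin or GC content. A preference for active genes in general therefore cannot be told apart from one for these lists. Lipid and cholesterol genes (40) had 55% (99.9th percentile) and 35% (98.9th percentile), with a fold of 55.5 at IDI1, an enzyme of the mevalonate pathway. In the siFOXA1 list the lipid list fell to the 96.1st percentile with a window of 2.5 kb and to the 87.7th with a −log10 q of at least 5.

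**Figure D3:**
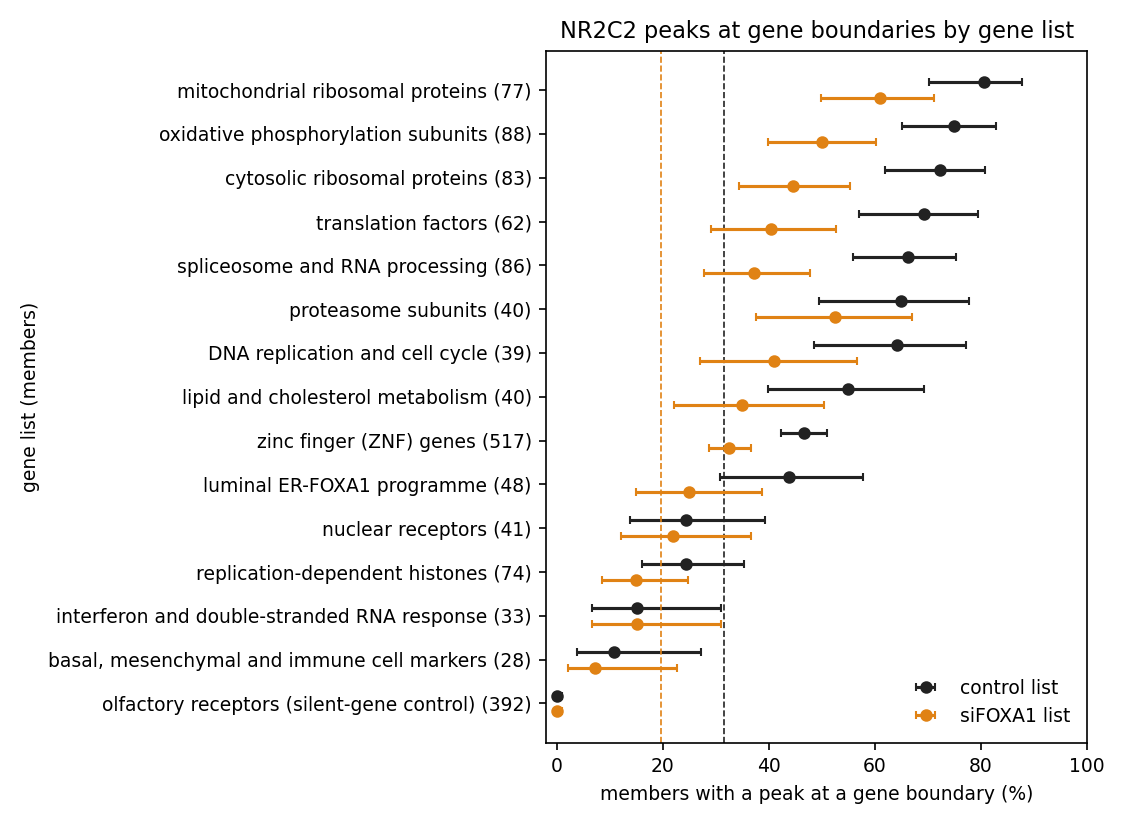
Percent of the members of each gene list (horizontal axis) with an NR2C2 peak within 1 kb of a gene boundary in the control and siFOXA1 lists, with 95% Wilson intervals over genes; the number of members is in parentheses and dashed lines mark all protein-coding genes (31.6% and 19.7%). Mitochondrial ribosomal protein genes were highest in both lists, at 80.5% and 61.0%.

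Markers of other cell types and silent genes carried few peaks. None of the 392 olfactory receptor genes had a boundary peak in either list, and both values were below all random lists. Of 28 basal, mesenchymal and immune markers, 10.7% had a control peak (0.63rd percentile) and 7.14% a siFOXA1 peak (4.01st percentile). One of these, 808 bp from a boundary of CD8A, had a fold enrichment of 37.3. Interferon and double-stranded RNA response genes (33) stood at 15.2% in both lists (1.84th and 26.2nd percentile), and all 5 members with a control peak, STAT2 and USP18 among them, also had a siFOXA1 peak. The low control share no longer stood apart with a −log10 q of at least 5, at the 4.94th percentile. Replication-dependent histone genes (74) had 24.3% and 14.9% (9.30th and 15th percentile). In the siFOXA1 list, a −log10 q of at least 5 brought histone genes to the 1.125th percentile, where they stood apart. It brought the basal, mesenchymal and immune markers to the 1.62nd, where they also stood apart. Nuclear receptor genes (41) had 24.4% and 22% (16.3rd and 65.9th percentile), and 8 of 10 with a control peak, NR2C1, NR2C2, NR1H2 and ESRRA among them, also had one in the siFOXA1 list. The control peak of NR1H2 lay 53 bp from a boundary of the neighbouring gene POLD1, which was nearer.

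Of the 6302 genes with a control boundary peak, 3838 (60.9%, 59.7 to 62.1) also had one in the siFOXA1 list, and 96 genes had one in the siFOXA1 list alone. Against random lists matched on control fold enrichment, none of the following lists stood apart except histone genes. The kept share was 75.8% for mitochondrial ribosomal protein genes (75.6th percentile), 65.2% for oxidative phosphorylation (75th), 60% for cytosolic ribosomal proteins (57.4th), 53.5% for translation factors (30.2nd), 54.4% for spliceosome genes (25.2nd), 80.8% for proteasome subunits (93.8th), 64.0% for replication genes (49.1st), 68.5% for ZNF genes (47.2nd) and 59.1% for lipid genes (51.0th). Nuclear receptors (80.0%) were at the 80.7th percentile and interferon genes (100%) at the 91.4th. Histone genes stood apart, with 11 of 18 kept (61.1%, 97.7th percentile), but not with a window of 2.5 kb (95.3rd) or a −log10 q of at least 5 (56.6th). Without matching on fold enrichment, mitochondrial ribosomal protein (99.4th), proteasome (98.2nd) and ZNF genes (99.3rd) stood apart and histone genes did not (49.7th).

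Genes of the luminal estrogen receptor and FOXA1 programme held both shared and control-only peaks. At their boundaries, 21 of 48 (43.8%, 96.3rd percentile) had a control peak and 12 (25%, 81.9th percentile) a siFOXA1 peak, and 11 of the 21 were kept (52.4%, 48.8th percentile of matched lists). With a window of 2.5 kb the control share was at the 99.8th percentile. Counting the gene and 10 kb around it, 34 of the 48 genes had 119 control peaks, of which 45 were shared (37.8%, 29.6 to 46.8) and 74 control-only. Random sets of control peaks of the same fold enrichment had a median of 39.5% shared, and the luminal value was at their 31.9th percentile. In the siFOXA1 list 23 genes had 51 peaks, 5 of them siFOXA1-only. TFF3, a secreted trefoil peptide, had 1 control peak with a fold enrichment of 26 (chromosome 21, 42315184 to 42315992), which was shared. The single peak of ERBB3, 93 bp from a boundary of the neighbouring gene PA2G4 and with a fold of 19.0, was shared, as were all 3 control peaks of GATA3, a luminal transcription factor, the strongest with a fold of 16.0. MLPH had 4 of 7 peaks shared and CTSD 3 of 4, with highest folds of 19.0 and 13.6. At ESR1, which encodes the estrogen receptor, 2 of 7 control peaks were shared, and the strongest one (chromosome 6, 151658069 to 151658430, fold 8.12, 75 reads) was control-only. At GREB1, an estrogen-induced gene, 1 of 6 was shared, and at XBP1 2 of 3. TFF1, another estrogen-induced gene, named after its values were seen, had 4 control peaks and none was shared. Only the peak 188 bp from a TFF1 boundary was nearest to TFF1. The others were inside a gene and nearest to the neighbouring gene TMPRSS3.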

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

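The tests of read depth, of a single enrichment factor, of the share of control-only peaks over 3 SDs (in place of an earlier noise test) and of shoulders over all deciles were set down before their outcomes were seen, while the shares expected to miss from counting error, the share of peaks over 3 SDs that were missing, the luminal percentile and the other tests in this part were chosen after results had been seen. Mitochondrial DNA, left out of the comparisons, held 10 control peaks and 2 siFOXA1 peaks above the input, with fold enrichments of 1.18 to 1.32 and 1.20 to 1.28.

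The siFOXA1 list was shorter than the control list. After their pileup was cut by the depth ratio of 0.941, 98.4% of control peaks would still pass the lowest −log10 p of the siFOXA1 list. That cutoff of 4.18 lay near the lowest −log10 p of the control list, 3.92, and 99.7% of control peaks passed it as listed. It is lenient in that it was the lowest value in the siFOXA1 list. The lower quartile of −log10 p in the siFOXA1 list was 10.1. No siFOXA1 peak was narrower than 218 bp, and the test asked for no width. Taken alone, that test does not exclude lower read depth. Other values argue against depth as the only cause at control peaks with a −log10 q of at least 10. Of these 7042 peaks, 1493 overlapped no siFOXA1 peak. The siFOXA1 list, at 0.941 times the control depth, reached down to a −log10 q of 1.32 and had a lower quartile of 6.83. Pileups of both lists were scaled to the same input. At 2568 strong peaks (control deciles 9 and 10, summits within 100 bp) the siFOXA1 pileup over background had a median of 0.760 times the control value. These peaks were chosen by high control values, which by itself can lower the ratio, and no choice by siFOXA1 values was made. A factor of that size at every site would leave 93.7% of control peaks above the same lenient cutoff, a share that does not exclude it. The log2 ratio itself differed between decile 9 (−0.54) and decile 10 (−0.30). Of the 4691 control peaks over 3 SDs of counting error above the reads they needed, 388 were control-only. This is 8.27%, against 0.116% expected from counting error and that factor together. The reads needed rest on the same lenient cutoff, so the margin may be overstated and the expected shares too low. As far as that cutoff holds, the gap between 8.27% and 0.116% argues against counting noise as the only cause at these 4691 peaks. Counting noise stays open at peaks nearer the threshold, which were listed because they passed it. Of control-only peaks, 5.99% lay over 3 SDs, as few as noise would need. Without regard to that selection, counting error would make 6.16% of control peaks miss the threshold, and 14.3% together with the factor, against 48.5% missing. Noise between libraries beyond counting, a lower immunoprecipitation yield that weighs more on weak sites and an effect of transfection may also contribute and were not tested, and a dependence on FOXA1 stays open, as the shared percent at luminal genes, which held 119 control peaks, was at the 31.9th percentile of equally strong peaks, which decides neither way.

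Peaks found only after FOXA1 siRNA lay away from gene boundaries. With an overlap of at least 1 bp, low fold enrichment of these peaks does not account for it, since the odds ratio within deciles of siFOXA1 fold enrichment was 6.63 (5.38 to 8.18). Without deciles, the odds ratio fell from 8.08 to 2.71 with summits within 100 bp and to 2.09 with a reciprocal overlap of 50%. Odds ratios within deciles were not computed under these 2 rules. A shift of signal from gene boundaries to other sites across the siFOXA1 libraries stays open, since at strong shared peaks the log2 ratio of pileup over background was lower at boundaries than at equally strong other peaks by a median difference of −0.16 (95% bootstrap interval −0.19 to −0.11), and by −0.07 (−0.10 to −0.03) without matching on strength, whereas it would also make boundary peaks of the control list go missing more often, and over its 6 stronger deciles the odds ratio of a boundary among shared peaks was 1.13 (1.01 to 1.27), or 1.11 (0.99 to 1.25) with the list in 50 classes of strength. The boundary share was 42.3% of the whole control list and 41.7% of the shorter siFOXA1 list, and at equal length, in differences that were not tested, 46.1% (45.1 to 47.2) and 41.7% (40.6 to 42.8) of the 8079 strongest peaks and 81.9% (79.1 to 84.4) and 78.1% (75.1 to 80.8) of the 808 strongest. Whether such a shift comes from the chromatin, the immunoprecipitation or the libraries cannot be read from 1 list per condition, and no biological explanation was tested for this pattern.

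Among the control peaks of lowest fold enrichment, those at gene boundaries were missing from the siFOXA1 list more often than others. Peaks of equal fold enrichment can differ in reads and −log10 p, which were not matched between boundary and other peaks. A first test for shoulders beside a stronger peak merged peaks within 500 bp over all deciles and gave an odds ratio of 0.922 (0.842 to 1.01), an interval that reaches 1 as shoulders would need. Without merging, the odds ratio was 0.634 over the 4 weakest deciles and 1.13 (1.01 to 1.27) over the other 6. In 50 classes of strength the latter was 1.11 (0.99 to 1.25), an interval that reaches 1. After these directions were seen, the test was restricted to the 4 weakest deciles. There the odds ratio with merged peaks was 0.665 (0.577 to 0.766), so shoulders account for little of the pattern in those deciles. The same shift of signal away from boundaries stays open, as does a true difference between weak sites at boundaries and elsewhere. A difference in −log10 p between boundary and other peaks of equal fold enrichment was not tested and also stays open. For the shift stands its difference of −0.16 at strong peaks (−0.07 without matching). Against it stands the odds ratio of 1.13 over the 6 stronger deciles, whose interval reached 1 in 50 classes of strength. The shared percent was higher at boundary than at intergenic peaks in deciles 6, 8 and 9 (97.7% and 94.6% in decile 9). It was lower at boundary than at intergenic peaks in deciles 5 and 7 (60.5% and 63.25% in decile 7). In both of these deciles it was higher at boundary peaks than inside genes (37.8% and 34.3% in decile 5, 60.5% and 59.6% in decile 7).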

How the results depend on the processing

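The comparison of siFOXA1-only with shared siFOXA1 peaks and its 10 alternatives were chosen after the data had been seen, and all other alternatives before. No paired analysis was possible because each condition has 1 pooled list with no values per replicate, and for the same reason no replicate could be left out. The motif tests with their alternatives and the random lists matched on GC content were not run, as no genome sequence was used here. The difference in strength kept its direction and its permutation p under all 8 alternatives, from 2.69 to 5.05 in fold enrichment, and the lower boundary share of siFOXA1-only peaks under all 10, with odds ratios from 2.09 to 10.9. The boundary odds ratio of shared against control-only peaks kept its direction under 11 alternatives (1.29 to 1.57) and reversed to 0.889 within deciles of control fold enrichment. There strong peaks, which were both more often shared and more often at a boundary (74.1% in the strongest decile), are compared among themselves. With peaks within 500 bp also merged, the odds ratio within deciles was 0.922 (0.842 to 1.01), an interval that reaches 1. The shared percent of control peaks, 51.5%, moved to 46.6% with a reciprocal overlap of 50%, 46.7% with summits within 100 bp, 53.9% with a −log10 q of at least 5, 59.3% with a fold enrichment of at least 5, 78.8% for control peaks with a −log10 q of at least 10, 73.4% with the control list shortened to the siFOXA1 length, and 52.7% with peaks within 500 bp merged. It was 51.4% with all sequences. The settings behind 78.8% and 73.4% leave out weak control peaks and no siFOXA1 peaks; the cause of the other moves was not tested. The number of gene lists standing apart with a high share was 9 in either list and from 8 to 10 under the alternatives. The number of lists whose kept share stood apart was 1, against 0 with a window of 2.5 kb, 0 with a −log10 q of at least 5, and 3 without matching on fold enrichment, for which the cause was not tested. Of the percentiles of single lists, 54 of boundary shares and 33 of kept shares stayed on their side of the limits, 3 and 3 came to stand apart, and 3 and 3 ceased to. Depth limits what can be said of weak sites, since no summit with a recovered read count had fewer than 17 reads in the control list or 16 in the siFOXA1 list.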

Other observations

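NR2C2 peaks also lay at genes that make no protein. Of 443 tRNA genes, 16.7% had a boundary peak in the control list and 8.13% in the siFOXA1 list, and 34 of the 74 with a control peak (45.9%) also had a siFOXA1 peak. Of 18177 lncRNA genes, 10.2% had a control and 6.18% a siFOXA1 peak, and 57.8% of those with a control peak kept one. These genes can lie close together or share a boundary with a protein-coding gene, and how often was not counted. The difference between tRNA and protein-coding genes was not tested. Pseudogenes that are not transcribed stood at 0.848% and 0.552% of 15212 genes. Across chromosomes the shared percent of control peaks ran from 43.2% on chromosome 21 to 57.0% on chromosome 19, and the siFOXA1-only percent of siFOXA1 peaks from 9.23% on chromosome 19 to 18.3% on chromosome 8.

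At strong peaks matched between the lists, the median log2 ratio of pileup over background, siFOXA1 over control, was −0.30 in the strongest decile of control fold enrichment (1328 peaks) and −0.54 in decile 9 (1240 peaks). It was −0.42 over 1601 boundary peaks and −0.35 over 967 other peaks before matching on strength. All these peaks were chosen by high control fold enrichment, which by itself can lower the ratio.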
